A study of Homo sapiens with 39 samples.

How the data were processed

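Transcript levels were measured in MCF-7 cells, an estrogen receptor-positive human breast cancer line, on 39 Affymetrix arrays, 3 for Control and 3 for each of 12 treatments. Per the labels' protocols, cells were kept for 24 h in hormone-free medium with charcoal-stripped serum and then exposed to the test substances for 48 h, with 3 wells in each of 3 independent experiments. The labels do not state that a replicate number marks 1 experiment, and where it does not, p-values measure only the spread between these arrays. Total RNA was extracted, amplified by single-primer isothermal amplification and biotin-labelled, per the labels' protocols. Groups and replicate numbers were taken from the sample titles and the labelled substances.

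The deposited values are log2 expression values, 1 column per array, and per the submitters' processing notes they were made with Affymetrix Expression Console and RMA. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of each transcript cluster. Tool versions, genome build and filters are not given in the sources used here. The table holds 70523 transcript clusters without missing values, from 1.13 to 14.6 on the log2 scale, and the array medians lay between 4.96 and 5.07. RMA compresses differences near the background, so fold changes of dim genes are understated. Arrays give no count of molecules, so only their number limits the precision stated here. Arrays of 1 group correlated between 0.986 and 0.9934 across transcript clusters, and no array pair held identical values.

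The platform annotation used here listed 25324 transcript clusters. Of these, 23781 carried exactly 1 gene symbol (22465 genes) and were tested, 1543 carried several symbols and named no gene, and the other 45199 clusters of the table were not listed. The gene tables given for this work matched 21497 tested clusters by gene identifier and changed no symbol. Where a gene had several clusters (479 genes), the one with the highest mean over all arrays stood for the gene in lists, and counts of calls are counts of clusters.

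Differential expression was tested with limma 3.58.1 in R 4.3.3. One linear model with a mean per group was fitted to all 39 arrays, so that the 13 groups shared 1 estimate of the spread with 26 degrees of freedom. Moderated two-sided tests (eBayes) were adjusted by the Benjamini-Hochberg method over the 23781 clusters of each comparison, and a cluster was called at an adjusted p under 0.05. The 12 treatments were compared with Control, and 8 direct comparisons were made between doses or substances. On simulated data with the spread of these arrays, 54% of the clusters changed by 0.5, 96% of those changed by 1 and 100% of those changed by 1.5 (log2) were called in the comparison of 1 nM estradiol with Control over 23781 clusters, with 13 false calls. The simulated clusters were independent, without a replicate effect, and 50 were changed per size. In comparisons with fewer changed clusters the share called can be lower.

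Of the 22 gene lists fixed in advance, 21 had measured members: estrogen-induced and estrogen-repressed genes, DNA replication and E2F targets, mitosis, cholesterol synthesis, fatty acid synthesis, unfolded protein response, NRF2 oxidative stress response, aryl hydrocarbon receptor targets, metal response, p53 targets, hypoxia response, interferon response, NF-kappaB inflammatory response, heat shock, immediate early genes, lysosome, luminal identity, basal and myoepithelial markers, stromal and immune markers, and ribosomal proteins. The list of mitochondrially encoded transcripts had 0 measured members. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 21 lists and 12 comparisons (252 tests), and again with a correlation estimated per list (also with the replicate block, added after seeing the data) and with fry, which tests whether the members move one way without comparing them with other genes. An estradiol signature was formed from the 65 genes called between 1 nM and 10 pM estradiol, 30 raised and 35 lowered. The score of an array is the mean of the raised minus the mean of the lowered genes, and groups were compared by exact two-sided permutation tests, in which 3 arrays against 3 cannot give a p below 0.1.

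The design, lists, alternatives and rule for named genes were fixed before the data were examined. The rule took, among called genes whose 3 arrays per group did not overlap, the 10 largest rises and the 10 largest falls per comparison, up to 4 called members per gene list, and a panel of 9 genes (TFF1, GREB1, PGR, CXCL12, PDZK1, CCNG2, MKI67, ESR1 and CYP1A1) in every comparison against Control. The alternatives were the replicate number as a block, only the 6 arrays compared, all 70523 clusters, bright clusters only, a further quantile normalization, the trend and robust options of eBayes, array weights, other signatures, and each array left out in turn. Background correction and probe summary were not varied, since only processed values were used.

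Replicate numbers were checked for pairing on the deviations from group means. Arrays with the same number had a median correlation of 0.296 and arrays with different numbers -0.17, and all 39 arrays were on average closest to arrays of their own number. Every pair exceeded a correlation of 0.1 in 18 of the 20 comparisons, the exceptions being Bisphenol A against Control (lowest 0.0836) and 10 ppm glyphosate against 1 nM estradiol (lowest 0.0526). In the other 18, the value with the replicate number as a block is given beside a result that it changes. Figures were drawn with matplotlib 3.10.9.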

Results

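Transcript levels of MCF-7 cells were available for 39 arrays in 13 groups of 3. The groups were untreated Control, 17β-estradiol (E2) at 10 pM, 100 pM and 1 nM, bisphenol A at 91 µg/l, glyphosate at 1 ppb, 100 ppb and 10 ppm, the surfactant polyethoxylated tallow amine (POEA) at 10 and 100 ppb, and Roundup, a formulated glyphosate herbicide, at 1 ppb, 100 ppb and 1 ppm of glyphosate (G). The title of the series names estrogenic effects of herbicide ingredients, so the comparisons asked which transcripts each substance changed and how far these were the ones that estradiol changed. Levels are deposited log2 values, changes are differences of group means on the log2 scale with the standard error (SE) of the limma model, and every group had n = 3 arrays. The number of arrays limits the precision.

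Estradiol at 1 nM against Control showed the response to the highest estradiol dose. MGP, which encodes matrix Gla protein, rose by 3.18 ± 0.37 (9.05-fold, adjusted p = 9.17e-07), from 4.79 ± 0.37 (SD) in Control to 7.97 ± 0.072. PGR, the progesterone receptor gene, rose by 2.84 ± 0.36 (7.14-fold, adjusted p = 4.84e-06), and GREB1, a classical estrogen-induced gene, by 2.70 ± 0.27 (6.52-fold, adjusted p = 7.51e-08). The transcription factor genes MYBL1 and MYB rose 5.5-fold and 3.05-fold, the neuropeptide Y receptor gene NPY1R rose 5.36-fold, and TFF1, which encodes a secreted trefoil peptide, rose 2.3-fold (adjusted p = 0.00122). Among the falls, EPAS1, which encodes a hypoxia-inducible transcription factor, changed by -1.83 ± 0.19 (adjusted p = 1.47e-07), the lipase gene LIPH by -1.80 ± 0.22 and the zinc finger gene SALL4 by -1.42 ± 0.12 (adjusted p = 5.18e-09). The chemokine gene CXCL12 rose by 0.70 ± 0.11, while ESR1, the estrogen receptor gene itself, differed by -0.06 ± 0.11 (adjusted p = 0.887). In all, 1104 transcript clusters were called, 635 higher and 469 lower (1075 genes), 98 of them by more than 2-fold. With the replicate number as a block, 2452 were called. Without E2_1nM replicate 1, E2_1nM replicate 2 or Control replicate 3 the count was 663, 547 or 544.

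By gene group, 26 of 47 measured estrogen-induced genes rose at 1 nM estradiol and 1, the aquaporin gene AQP3 (-0.80, named after its value was seen), fell, or 37 in both directions adjusted over the list alone (camera adjusted p = 1.38e-31, and adjusted p = 0.000173 with an estimated correlation). Of 17 estrogen-repressed genes, 7 fell and none rose, 10 adjusted over the list alone (camera adjusted p = 1.49e-12, and adjusted p = 0.000123 with an estimated correlation), and 11 fell with the block. They included PSCA (-1.68), TP53INP1 (-1.04), the interleukin receptor gene IL1R1 (-1.04) and YPEL3 (-0.72). Genes of DNA replication and E2F targets rose in 22 of 39 cases, 36 adjusted over the list alone, among them DTL (1.12), the exonuclease gene EXO1 (0.89) and RRM2, a subunit of ribonucleotide reductase (0.83). Mitosis genes rose in 23 of 34 cases, 31 adjusted over the list alone, among them NDC80 of the kinetochore (0.91), DLGAP5 (0.88) and MYBL2 (0.85). The median change was 0.451 and 0.661 in these lists, whose camera adjusted p of 6.08e-24 and 7.88e-25 became adjusted p = 0.254 and adjusted p = 0.272 with an estimated correlation . With the block as well, these were 0.00145 and 0.0157, and 34 and 32 members rose. The proliferation marker gene MKI67 rose by 0.69 ± 0.20 (adjusted p = 0.0413), and CCNG2, a cyclin gene repressed by estrogen, fell by 0.47. In fits without the block, leaving out 1 array could end these calls. Adjusted p without 1 array reached 0.18 for EXO1, 0.255 for RRM2, 0.118 for NDC80 and 0.173 for DLGAP5. It reached 0.0613 for MYBL2, 0.24 for MKI67 and 0.0749 for CCNG2. Such fits leave the replicate numbers unbalanced between the groups. They cannot tell dependence on 1 array from differences between the numbers, and none was made with the block. Leaving out Control replicate 3 ended each of these calls, E2_1nM replicate 2 all but that of MYBL2, E2_1nM replicate 1 or Control replicate 2 those of EXO1, RRM2, DLGAP5 and MKI67, and E2_1nM replicate 3 that of MKI67. With the block on all arrays each of these calls was kept. Their lowest adjusted p over the alternatives ran from 5.12e-08 for MYBL2 to 4.32e-05 for MKI67.

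Metabolic gene groups moved by less. Of 20 cholesterol synthesis genes 1, the reductase gene DHCR7, rose by 0.45 (adjusted p = 0.027, up to 0.296 without 1 array, the call ending without E2_1nM replicate 1, E2_1nM replicate 2 or Control replicate 3), 4 higher and 1 lower adjusted over the list alone, with a list median of 0.254. Of 10 fatty acid synthesis genes, ELOVL5 (0.34) and FADS2 (0.28) rose, 2 adjusted over the list alone, though neither was called without E2_1nM replicate 2, nor FADS2 without E2_1nM replicate 1, Control replicate 2 or Control replicate 3 (adjusted p up to 0.0589 and 0.151). Of 17 lysosome genes 2 rose, with GLA, the gene of alpha-galactosidase A, at 1.47 ± 0.15 (adjusted p = 1.47e-07) and CTSD at 0.39 (adjusted p = 0.0676 without E2_1nM replicate 2). Another 3 fell, among them the acid ceramidase gene ASAH1 (-0.60) and CTSL (-0.48), or 5 adjusted over the list alone. Camera adjusted p was 0.00107, 0.0473 and 0.00916 for these lists, against adjusted p = 0.971, 0.956 and 0.45 with an estimated correlation. With the block as well the cholesterol synthesis list was called (adjusted p = 0.0197, 9 members higher and 1 lower), and the block alone called 4 fatty acid synthesis genes higher and 2 lysosome genes higher and 7 lower. Of 20 interferon response genes and 16 ribosomal protein genes limma called 0, also adjusted over the list alone (medians -0.165 and 0.109, camera adjusted p = 0.0281 and 0.0145, then adjusted p = 0.985 and adjusted p = 0.971 with an estimated correlation). With the block 1 interferon response gene fell and 2 ribosomal protein genes rose. PDZK1 differed by 0.65 ± 0.24 (adjusted p = 0.152, 0.00873 with the block, 0.00873 to 0.568 over the alternatives). The aryl hydrocarbon receptor target CYP1A1 differed by -1.02 ± 0.57 (adjusted p = 0.438, 8.42e-06 with the block, 8.42e-06 to 0.837 over the alternatives). Control replicate 1 scored -1.864 on the estradiol signature, against -2.011 and -2.059 in the other Control arrays, so it lay higher in estradiol-responsive genes.

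Estradiol at 100 pM gave changes of similar size. PGR rose by 2.96 ± 0.36 (7.8-fold, adjusted p = 2.84e-06), MGP by 2.85 ± 0.37 (7.2-fold), GREB1 by 2.73 ± 0.27 (6.64-fold, adjusted p = 1.07e-07) and TFF1 by 1.21 ± 0.23 (2.32-fold, adjusted p = 0.00119). EPAS1 fell by 1.81, RND1 by 1.56, SAT1, the gene of a polyamine acetyltransferase, by 1.53, and the apolipoprotein gene APOD by 1.39. Estrogen-induced genes rose in 30 of 47 cases and AQP3 fell, 37 adjusted over the list alone. Of the estrogen-repressed genes 5 of 17 fell, 8 adjusted over the list alone (adjusted p = 0.000123 and 0.000173 for both lists with an estimated correlation), and 11 fell with the block. Of DNA replication and E2F targets 27 of 39 rose, 35 adjusted over the list alone. Of mitosis genes 24 of 34 rose, 32 adjusted over the list alone (adjusted p = 0.146 and adjusted p = 0.218 for both lists with an estimated correlation). With the block as well both lists were called (0.000621 and 0.00998). Of cholesterol synthesis genes 2 of 20 rose, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 2.13e-05, then adjusted p = 0.956 with an estimated correlation). With the block 11 rose and 1 fell, and with both the list was called (adjusted p = 0.00567). Of fatty acid synthesis genes 2 of 10 rose, 4 with the block, and of ribosomal protein genes limma called 0 of 16, 2 higher with the block (medians 0.205 and 0.0919, camera adjusted p = 0.00656 and 0.0131, then adjusted p = 0.758 and adjusted p = 0.971 with an estimated correlation). CXCL12 rose by 0.69 (adjusted p = 0.000103), PDZK1 by 0.90 (adjusted p = 0.0247) and MKI67 by 0.75 (adjusted p = 0.023). CCNG2 fell by 0.44 (adjusted p = 0.00982), and ESR1 differed by 0.04. The calls of PDZK1 and MKI67 ended without either E2_100pM replicate 1 or 2 or Control replicate 2 or 3 (adjusted p up to 0.272 and 0.153). That of CCNG2 ended without E2_100pM replicate 1 or Control replicate 3 (up to 0.115). CYP1A1 differed by -1.15 (adjusted p = 0.349, 1.54e-06 with the block, 1.54e-06 to 0.728 over the alternatives). The count was 1158, with 779 higher and 379 lower (1122 genes), and 2470 with the block. At 1 nM, 527 of those higher and 320 of those lower were called in the same direction, against 20.8 and 7.47 for independent lists, although both comparisons share the Control arrays. Without E2_100pM replicate 1, E2_100pM replicate 2, Control replicate 2 or Control replicate 3 the count was 632, 635, 711 or 582.

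Estradiol at 10 pM, the lowest dose, changed fewer transcripts. GREB1 rose by 1.69 ± 0.27 (3.22-fold, adjusted p = 0.00601), PGR by 1.77 ± 0.36 (3.4-fold, adjusted p = 0.0331), and the stanniocalcin genes STC1 and STC2 by 1.32 and 0.67 (adjusted p = 0.00895 and 0.00601). IL1R1 fell by 0.68 (adjusted p = 0.00868), EPAS1 by 0.92 and SALL4 by 0.58. TFF1 differed by 0.79 ± 0.23 (adjusted p = 0.309, 0.0221 with the block, 1.73e-07 to 1 over the alternatives), CCNG2 by -0.25 (adjusted p = 0.679, 0.0149 with the block, 0.0149 to 1 over the alternatives), MKI67 by 0.32, CXCL12 by 0.18, PDZK1 by 0.37, ESR1 by 0.10 and CYP1A1 by -0.42, none of them called. Of the estrogen-induced genes 5 rose, 23 adjusted over the list alone, and 1 estrogen-repressed gene fell, 4 adjusted over the list alone (adjusted p = 0.000173 and adjusted p = 0.00758 with an estimated correlation). With the block 20 rose and 6 fell. Limma called 0 genes of DNA replication or mitosis, 14 and 0 adjusted over the lists alone, with medians of 0.292 and 0.318 (camera adjusted p = 1.55e-23 and 7.07e-15, then adjusted p = 0.254 and adjusted p = 0.673 with an estimated correlation). With the block 16 of 39 DNA replication genes and 4 of 34 mitosis genes rose, and with both the lists were called (adjusted p = 0.00109 and 0.0473). Camera also called interferon response and lysosome genes lower and ribosomal protein genes higher (medians -0.14, -0.0934 and 0.0684, adjusted p = 0.00369, 0.00916 and 0.00734). With an estimated correlation these were adjusted p = 0.971, 0.45 and 0.971, while 1 lysosome gene was called higher, and another lower with the block. The count was 36, with 22 higher and 14 lower, and 324 with the block. Of the 22 and 14, 21 and 13 were called in the same direction at 1 nM, against 0.587 and 0.276 for independent lists. Both comparisons share the Control arrays, and the overlap that this alone gives was not computed. The count was 0 without Control replicate 2 or Control replicate 3, so in fits without the block no call at this dose holds without either. It was 6, 10 or 7 without E2_10pM replicate 1, 2 or 3. These fits left the replicate numbers unbalanced, so they cannot tell dependence on 1 array from differences between the numbers.

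The direct comparison of 1 nM with 10 pM estradiol tested the effect of dose without Control arrays. MGP was higher at 1 nM by 2.32 ± 0.37 (5-fold, adjusted p = 0.00117), MYBL1 by 1.65 ± 0.20 (3.13-fold, adjusted p = 6.43e-05), the Notch target HEY2 by 1.00 and the kinase gene FRK by 0.93. SALL4 was lower, at -0.85 ± 0.12 (adjusted p = 0.000478), as were the vesicle transport gene RAB27B (-0.86) and the epithelial transcription factor gene GRHL3 (-0.77). The count was 66, with 31 higher and 35 lower, and 374 with the block. Without E2_1nM replicate 1 or 2, or without E2_10pM replicate 1, 2 or 3, it was 29, 14, 22, 33 or 39.

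Bisphenol A, a plastic monomer that binds estrogen receptors, was compared with Control at 91 µg/l. PGR rose by 2.07 ± 0.36 (4.18-fold, adjusted p = 0.00212), GREB1 by 1.71 ± 0.27 (3.28-fold, adjusted p = 0.000439), STC1 2.82-fold (adjusted p = 0.000433) and MYB by 1.23 (adjusted p = 0.00056). EPAS1 changed by -1.53 ± 0.19 (adjusted p = 6.06e-05), LIPH by -1.35 (adjusted p = 0.000674) and IL1R1 by -0.87 (adjusted p = 6.2e-05). Among estrogen-induced genes 13 of 47 rose and AQP3 fell, 26 adjusted over the list alone. Of 17 estrogen-repressed genes 3 fell, 7 adjusted over the list alone (for both lists adjusted p = 0.000309 and adjusted p = 0.000173 with an estimated correlation). Of DNA replication and E2F targets 4 of 39 rose, 30 adjusted over the list alone (adjusted p = 0.176 with an estimated correlation), including DTL at 0.98 (adjusted p = 0.0488, up to 0.296 without 1 array and called only when Control replicate 1 was the array left out). Of mitosis genes limma called 0, 23 adjusted over the list alone (median 0.457, camera adjusted p = 1.33e-20, then adjusted p = 0.388 with an estimated correlation). Cholesterol synthesis genes were higher by camera (median 0.138, adjusted p = 0.022, then adjusted p = 0.994 with an estimated correlation), and limma called 0 of 20, also adjusted over the list alone. Of 17 lysosome genes 15 were lower (median -0.139, camera adjusted p = 0.000158, fry adjusted p = 0.0416, then adjusted p = 0.146 with an estimated correlation), and 5 fell and 1 rose adjusted over the list alone. With an estimated correlation and the block, the DNA replication, mitosis and lysosome lists were called (adjusted p = 0.000621, 0.0201 and 0.0379). Among all genes GLA (1.02) and ASAH1 (-0.56) were called, ASAH1 not without Bisphenol A replicate 3 or Control replicate 2 (adjusted p up to 0.0705). TFF1 differed by 0.91 ± 0.23 (adjusted p = 0.051), CXCL12 by 0.32, PDZK1 by 0.64, CCNG2 by -0.34, MKI67 by 0.48, ESR1 by 0.09 and CYP1A1 by -0.58, none of them called. Some alternatives called each of these but ESR1. Over the alternatives adjusted p ran from 8.99e-09 to 0.404 for TFF1, 0.0133 to 0.562 for CXCL12, 0.00103 to 0.748 for PDZK1 and 0.000202 to 0.651 for CCNG2. It ran from 0.00437 to 0.873 for MKI67, 0.405 to 1 for ESR1 and 0.00839 to 1 for CYP1A1. The count was 196, with 105 higher and 91 lower (195 genes), and 1056 with the block. In fits without the block it was 74 without Bisphenol A replicate 1, 120 without Bisphenol A replicate 2, 89 without Control replicate 2 and 62 without Control replicate 3.

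Of the transcript clusters that bisphenol A raised, 101 of 105 were also called higher at 1 nM estradiol, and 89 of the 91 lowered were also called lower, against 2.8 and 1.79 for independent lists, with none in the opposite direction and the Control arrays shared. Over all tested clusters both changes correlated at 0.838. Simulated treatments that shared the Control arrays, neither with an effect, gave 0.153 to 0.738 (genes are not independent replicates). Since 1 nM estradiol did have an effect, this range does not decide how much of the 0.838 the shared Controls gave. Called directly against 1 nM estradiol, bisphenol A arrays were lower in MYBL1 (-1.46 ± 0.20, adjusted p = 0.00075), HEY2 (-0.90, adjusted p = 0.0248), C12orf60 (-0.81, adjusted p = 0.0179), TIAM1 (-0.54, adjusted p = 0.0274) and TFAP2C (-0.43, adjusted p = 0.0248) and higher in SALL4 (0.72 ± 0.12, adjusted p = 0.0158), which 1 nM estradiol lowered further. These were the 6 calls, 55 with the block. Without Bisphenol A replicate 1, 2 or 3 there were 3, 2 or 3, and without E2_1nM replicate 1, 2 or 3 there were 2, 2 or 3. MYBL1 was called in each of these (adjusted p up to 0.0139).

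**Figure D1:**
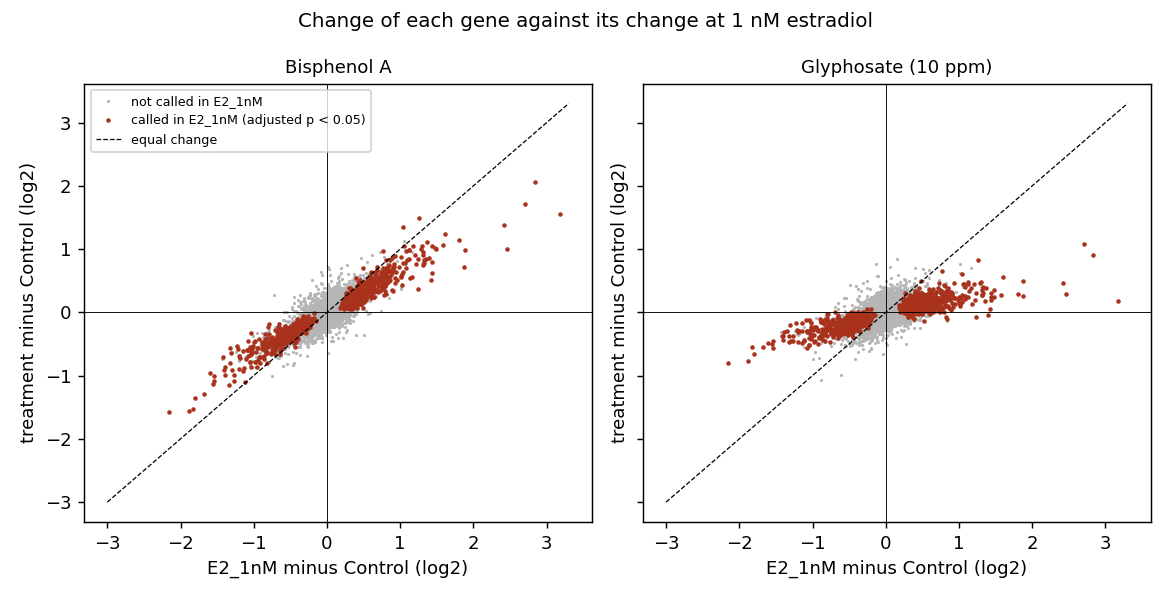
Each point is a tested transcript cluster, with its log2 change at 1 nM estradiol against Control on the x axis and its log2 change with bisphenol A (left) or 10 ppm glyphosate (right) against Control on the y axis; red points were called at 1 nM estradiol and the dashed line marks equal change. The correlation across clusters was 0.838 with bisphenol A and 0.628 with 10 ppm glyphosate, and all axes share the same Control arrays.

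Glyphosate at 10 ppm was compared with Control to ask whether the highest dose changed these transcripts. GREB1 differed by 1.09 ± 0.27 (2.12-fold, adjusted p = 0.992, 6.53e-08 to 1 over the alternatives), PGR by 0.90 ± 0.36 (1.87-fold) and TFF1 by 0.45 ± 0.23 (1.37-fold, adjusted p = 0.992, 0.000664 to 1 over the alternatives), while CXCL12 differed by 0.11, PDZK1 by 0.10, CCNG2 by -0.18, MKI67 by 0.08, ESR1 by 0.12 and CYP1A1 by -0.12. GREB1 lay at 8.22 to 8.49 in these arrays and at 6.83 to 7.74 in Control. The spread shared by all groups includes POEA (10 ppb) replicate 1, with GREB1 at 8.63 against 6.74 and 6.98 in its group. Without that array and Control replicate 1, and with the block, the SE of GREB1 was 0.11. Estrogen-repressed genes were lower as a list (median -0.178, camera adjusted p = 0.000176, adjusted p = 0.0321 with an estimated correlation), with 1 of 17 called adjusted over the list alone. Estrogen-induced genes were higher by camera (median 0.137, adjusted p = 7.92e-10), but had adjusted p = 0.0889 with an estimated correlation (0.0197 with the block as well), and 3 of 47 were called adjusted over the list alone. DNA replication and mitosis genes were higher by camera (medians 0.176 and 0.125, adjusted p = 6.39e-07 and 0.00731, then adjusted p = 0.971 and adjusted p = 0.994 with an estimated correlation). Interferon response and lysosome genes were lower (medians -0.0858 and -0.0873, camera adjusted p = 0.0473 and 0.00369, then adjusted p = 0.994 and adjusted p = 0.344 with an estimated correlation). Limma called 0 single transcripts among all tested, and 1 higher and 1 lower with the block. At an unadjusted p under 0.05 there were 972, and 1707 with the block, where chance gives 1189. Leaving out Control replicate 1, the array that scored highest of the Controls on the estradiol signature, gave 1 call. Leaving out both that array and POEA (10 ppb) replicate 1, with the block, an alternative chosen after seeing the data, gave 49. Leaving out a Control array for its high score moves the comparison toward the estradiol direction. Of the 635 clusters raised by 1 nM estradiol 601 were positive and of the 469 lowered 464 were negative, but the shared Controls contribute to this. Over all tested clusters the changes correlated at 0.628 with those at 1 nM estradiol (genes are not independent replicates). This lay inside the 0.153 to 0.738 of simulated treatments without effect that shared the Controls. The covariance, 0.0153, lay above the simulated 0.00156 to 0.0134. In the simulation neither treatment had an effect, unlike 1 nM estradiol, so neither range decides whether 10 ppm glyphosate had one. The other herbicide comparisons correlated at 0.0627 to 0.326 with 1 nM estradiol.

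Compared with 1 ppb glyphosate, which uses no Control array, 10 ppm glyphosate raised STC2 by 0.67 ± 0.10 (1.6-fold, adjusted p = 0.00423). IL1R1 was lower, at -0.74 ± 0.11 (adjusted p = 0.00423), as were the extracellular matrix gene TGFBI at -0.62 ± 0.11 (adjusted p = 0.0385) and the calpain inhibitor gene CAST at -0.45 ± 0.08 (adjusted p = 0.0295). These 4 were the only calls, 73 with the block, and CAST was not called when any 1 of the 6 arrays was left out (adjusted p 0.0544 to 0.151). Without Glyphosate (10 ppm) replicate 1 or 2 there were 0 or 2 calls, and without Glyphosate (1 ppb) replicate 1, 2 or 3 there were 2, 1 or 0. Against 1 nM estradiol, 10 ppm glyphosate was lower in MGP (-2.99 ± 0.37, adjusted p = 9.62e-06), MYBL1 (-2.16), PGR (-1.93 ± 0.36, adjusted p = 0.0031) and GREB1 (-1.62 ± 0.27, adjusted p = 0.000661), and higher in EPAS1 (1.29 ± 0.19, adjusted p = 0.000158) and SALL4 (1.05 ± 0.12). That comparison called 289 clusters, 134 higher and 155 lower, and 1135 with the block. It called 133, 93, 123 or 129 without E2_1nM replicate 1, E2_1nM replicate 2, Glyphosate (10 ppm) replicate 2 or Glyphosate (10 ppm) replicate 3. PGR was not called without Glyphosate (10 ppm) replicate 3 (adjusted p = 0.0541).

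**Figure D2:**
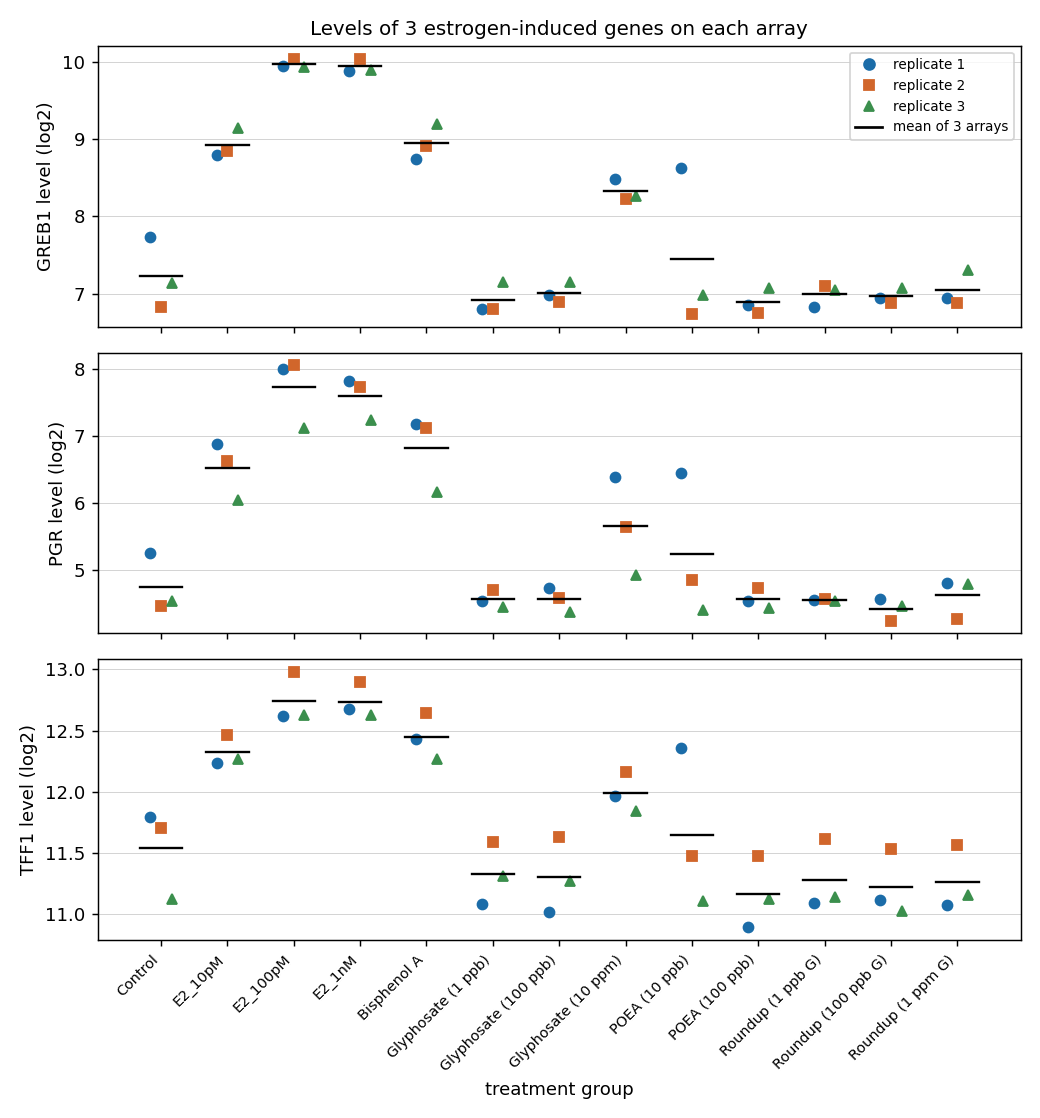
Log2 level of GREB1, PGR and TFF1 in each of the 39 arrays, by group on the x axis, with a marker per replicate number and a black bar at the mean of 3. GREB1 averaged 7.24 in Control, 8.32 at 10 ppm glyphosate and 9.94 at 1 nM estradiol.

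Glyphosate at 1 and 100 ppb, POEA at 10 and 100 ppb and Roundup at all 3 doses were each compared with Control for the same question. Across these 7 comparisons GREB1 differed by -0.35 to 0.21, PGR by -0.33 to 0.48, TFF1 by -0.37 to 0.11, CXCL12 by -0.04 to 0.10, PDZK1 by -0.21 to -0.01, CCNG2 by -0.06 to 0.05, MKI67 by -0.20 to -0.05, ESR1 by -0.11 to 0.03 and CYP1A1 by 0.20 to 0.40, with a lowest adjusted p of 0.744. Limma called 0 transcript clusters in each, also with the block. The counts at an unadjusted p under 0.05 were 324 and 951 for glyphosate at 1 and 100 ppb, 1398 and 707 for POEA at 10 and 100 ppb, and 681, 866 and 395 for Roundup at 1 ppb, 100 ppb and 1 ppm. With the block they were, in the same order, 556 and 1452, 2106 and 1100, and 1168, 1431 and 646. Without Glyphosate (1 ppb) replicate 2 there was 1 call in the first, and without Roundup (1 ppb G) replicate 1 there was 1 call with Roundup at 1 ppb. POEA (10 ppb) replicate 1 scored -1.376 on the estradiol signature, next to the lowest of the 10 pM estradiol arrays at -1.374, while the other arrays of its group scored -2.018 and -1.952. The 10 pM arrays served to choose the signature genes, so their scores do not mark the level of exposure of another array.

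In these 7 comparisons camera called some gene groups at its preset correlation. Mitosis genes had negative medians in all 7, from -0.205 at 100 ppb Roundup, with 32 of 34 members negative, to -0.0687 at 1 ppm Roundup, and were called by camera in 6 (adjusted p = 4.13e-09 at 1 ppb Roundup), with adjusted p between 0.956 and 0.994 with an estimated correlation. Without Control replicate 1 and POEA (10 ppb) replicate 1, an alternative chosen after seeing the data, 5 of these 6 calls ended (adjusted p = 0.158 and 0.982 at 1 and 100 ppb glyphosate, 0.769 at 100 ppb POEA, 0.239 and 0.186 at 1 and 100 ppb Roundup). The direction turned at 1 ppb glyphosate, and only the call at 10 ppb POEA was kept (0.000977). Estrogen-induced genes were lower by camera at 1 ppb glyphosate (median -0.0541, adjusted p = 0.0351), 100 ppb POEA (-0.0798, adjusted p = 0.000927), 100 ppb Roundup (-0.0525, adjusted p = 0.016) and 1 ppm Roundup (-0.0552, adjusted p = 0.0225). With an estimated correlation these were adjusted p = 0.971, 0.697, 0.956 and 0.971, and without the same 2 arrays 0.871, 0.516, 0.836 and 0.928, with the direction turned at 1 ppb glyphosate and 1 ppm Roundup. DNA replication genes were lower by camera at 1 and 100 ppb Roundup (medians -0.0409 and -0.0528, adjusted p = 0.0155 and 0.00734, then adjusted p = 0.994 with an estimated correlation for both). Without the same 2 arrays both calls ended with the direction turned (0.594 and 0.769), and the list turned and was called higher at 1 ppb glyphosate (0.00293) and 1 ppm Roundup (0.00741). Ribosomal protein genes were lower at 100 ppb of glyphosate, POEA and Roundup (medians -0.0368, -0.047 and -0.022, adjusted p = 0.0183, 0.00386 and 0.0225). With an estimated correlation these were adjusted p = 0.971, 0.956 and 0.971, and without the same 2 arrays 0.0568, 0.015 and 0.0599. Interferon response genes were lower by camera at 100 ppb POEA (median -0.115) and 100 ppb Roundup (median -0.131), with adjusted p = 0.956 with an estimated correlation for both. Without the same 2 arrays these were 0.0599 and 0.126, and the list was called higher at 10 ppb POEA and 1 ppb Roundup (0.0157 and 0.00669). At 1 ppb glyphosate the NRF2 oxidative stress and lysosome lists were higher (medians 0.0836 and 0.046, camera adjusted p = 0.0316 and 0.0473, then adjusted p = 0.985 and adjusted p = 0.815 with an estimated correlation), as were the immediate early genes at 100 ppb Roundup (median 0.0894, camera adjusted p = 0.0494, then adjusted p = 0.977 with an estimated correlation). Without the same 2 arrays these were 0.683, 0.683 and 0.488. With an estimated correlation no list was called in any of the 7. With the block as well, the NRF2 list and aryl hydrocarbon receptor targets were called at 1 ppb glyphosate (adjusted p = 0.0197 and 0.0373). Control replicate 1, which lay higher in estradiol-responsive genes, takes part in each.

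In none of the 12 comparisons against Control did camera call 10 of the 21 lists at the preset correlation. Their lowest adjusted p was 0.293 for the unfolded protein response, 0.264 for aryl hydrocarbon receptor targets, 0.266 for the metal response, 0.118 for p53 targets, 0.593 for the hypoxia response, 0.131 for the NF-kappaB inflammatory response, 0.116 for heat shock, 0.101 for luminal identity, 0.161 for basal and myoepithelial markers and 0.159 for stromal and immune markers. Fry called the unfolded protein response higher at 100 pM and 1 nM estradiol (adjusted p = 0.0129 and 0.0416, against adjusted p = 0.815 and adjusted p = 0.971 with an estimated correlation). Of its 23 members 5 rose at 100 pM, among them HYOU1 (0.33, adjusted p = 0.00674), not called without Control replicate 2 or E2_100pM replicate 1 (up to 0.0781). At 1 nM 4 rose (7, and 3 lower, with the block), among them CRELD2 (0.28, adjusted p = 0.0051), not called without Control replicate 3 or E2_1nM replicate 1 (up to 0.0663). HERPUD1 fell there (-0.31, adjusted p = 0.026), but was called in only some of the fits without 1 array (up to 0.182). Other single members were called at 1 nM estradiol, among them TIPARP (0.52, adjusted p = 7.31e-06), a target of the aryl hydrocarbon receptor, and the luminal transcription factor genes TFAP2C (0.50) and ELF3 (-0.77). The hypoxia response members EGLN3 and LDHA were called in opposite directions, at -0.62 and 0.51, LDHA not without E2_1nM replicate 1, E2_1nM replicate 2 or Control replicate 3 (adjusted p up to 0.111). With the block, camera also called aryl hydrocarbon receptor targets at 100 pM estradiol (adjusted p = 0.0488) and 1 ppb glyphosate (0.00649), p53 targets at 1 nM estradiol (0.028), and cholesterol and fatty acid synthesis at 10 pM estradiol (0.00224 and 0.022). It also called estrogen-induced genes at 100 ppb glyphosate (0.0182) and 1 ppb Roundup (0.0131), DNA replication at 100 ppb POEA (0.0131), immediate early genes at 1 ppb and 1 ppm Roundup (0.0127 and 0.0126) and mitosis at 1 ppm Roundup (0.00439), and no longer interferon response genes at 10 ppm glyphosate (0.0524). Over their alternatives the adjusted p of these lists ran from 0.00103 to 0.994. Of the list calls gained with the block, only that of aryl hydrocarbon receptor targets at 1 ppb glyphosate was kept with an estimated correlation as well.

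**Figure D3:**
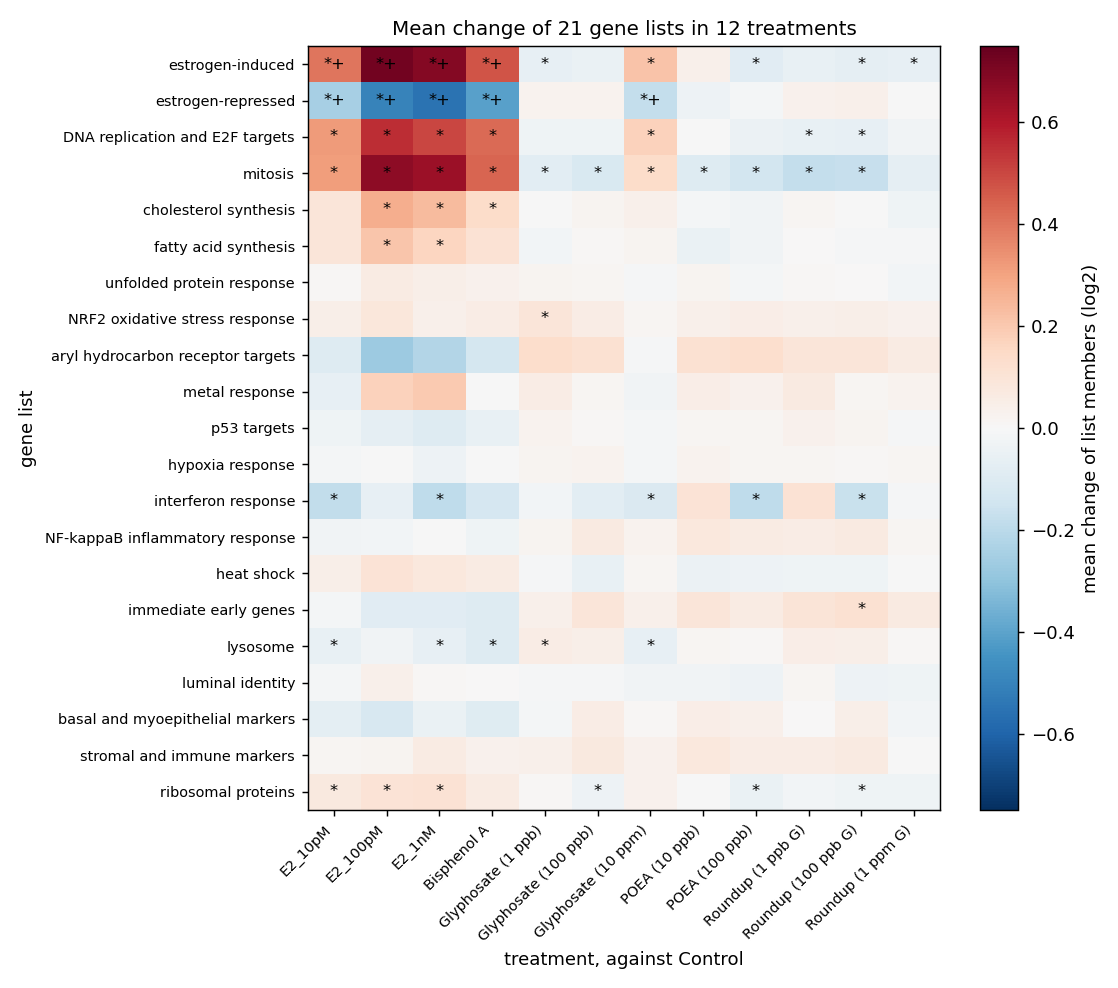
Mean log2 change of the measured members of 21 gene lists (y axis) in 12 treatments against Control (x axis), as color. A star marks camera adjusted p under 0.05 at the preset correlation and a plus the same with an estimated correlation, which the estrogen-induced list reached at all 3 estradiol doses and with bisphenol A.

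The remaining direct comparisons asked whether dose or formulation changed transcripts. Limma called 0 clusters between 100 and 10 ppb POEA, between 1 ppm and 1 ppb Roundup, and between Roundup and glyphosate at 1 ppb or at 100 ppb of glyphosate, also with the block. The counts at an unadjusted p under 0.05 were 427, 658, 661 and 428, and 683, 1085, 1090 and 643 with the block. The Roundup dose comparison gave 2 calls without Roundup (1 ppb G) replicate 1.

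The estradiol signature summarised each array by the 65 genes that differed between 1 nM and 10 pM estradiol. The 3 Control arrays scored -1.978 on average (SD 0.102). Bisphenol A scored 1.079 ± 0.113 above Control and 100 pM estradiol 1.834 ± 0.111 above Control. Glyphosate at 10 ppm scored 0.366 ± 0.113 above Control, with arrays at -1.531, -1.631 and -1.674, all above the 3 Controls. The exact two-sided permutation p was 0.1 for each of the 3, the smallest that 3 arrays against 3 can give, and 0.333 adjusted over 10 comparisons. Against 1 ppb glyphosate, the 10 ppm arrays scored 0.443 ± 0.113 higher (exact permutation p = 0.1). POEA at 10 ppb scored 0.196 higher, but -0.007 without POEA (10 ppb) replicate 1. The other 6 groups differed from Control by -0.077 to -0.042.

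**Figure D4:**
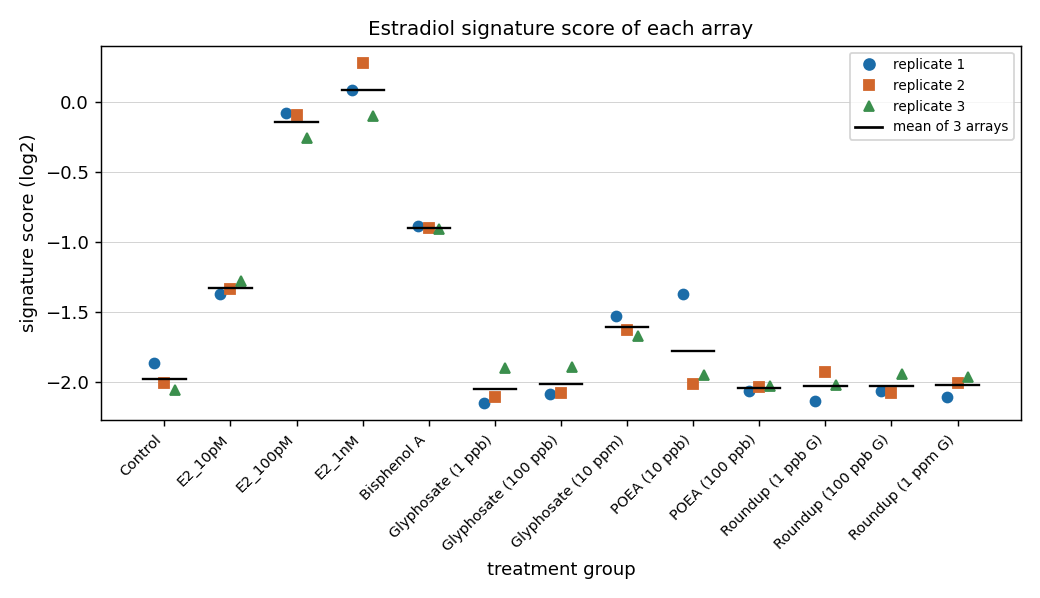
Estradiol signature score (log2, mean of 30 raised minus mean of 35 lowered genes) of each of the 39 arrays on the y axis by group on the x axis, with a marker per replicate number and a black bar at the mean of 3; the genes were chosen on the 1 nM and 10 pM arrays. Bisphenol A arrays lie at -0.887 to -0.912 and the 10 ppm glyphosate arrays at -1.531 to -1.674, above the Control arrays at -1.864 to -2.059.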

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

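The test of array quality or scaling in genes chosen without the array, of exchanged labels, of a response to POEA, of exposure to about 10 pM estradiol and of the shared Control arrays, and the alternatives that leave out POEA (10 ppb) replicate 1 and Control replicate 1, were chosen after the results were seen.

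The difference between 1 nM and 10 pM estradiol was tested directly and called 66 transcript clusters, led by MGP and MYBL1. Bisphenol A and 1 nM estradiol, which changed largely shared transcripts against Control, differed directly in 6 clusters. Glyphosate at 10 ppm differed from 1 ppb glyphosate in 4 clusters (STC2, IL1R1, TGFBI and CAST) and from 1 nM estradiol in 289. Outside the main measurement, 545 of the 46742 clusters without a single gene symbol were called at 1 nM estradiol against Control, 234 higher and 311 lower, when the whole table was tested. The same clusters gave 499 calls at 100 pM estradiol, 69 with bisphenol A and 5 at 10 pM.

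Glyphosate at 10 ppm carried part of the estradiol profile in all 3 arrays. Material from a 1 nM well mixed into these wells would give every gene the same share of the 1 nM response, but genes responsive at 10 pM showed a larger share than the rest, 42.8 against 20.7% (difference 0.222 ± 0.0332, bootstrap SE over 130 genes). The share tested and the 10 pM share that sorted the genes are divided by the same 1 nM response. Noise alone can therefore give a difference of this sign. Its size without an effect was not computed, so mixing stays open. Chance values of the shared Control arrays are argued against by the signature difference from 1 ppb glyphosate, 0.443 ± 0.113 with no Control array used. Across genes, the change of 10 ppm against 1 ppb glyphosate correlated with that of 1 nM against 10 pM estradiol at 0.391. Simulations in which neither change held an effect gave -0.392 to 0.374 (genes are not independent replicates). The estradiol change did hold an effect, unlike in these simulations, so this range does not decide whether the glyphosate change held one. A weak response to 10 ppm glyphosate may be the source and remains a hypothesis, and a low-dose estradiol trace in these wells stays open. The slopes of the 3 arrays on the 10 pM response were 0.806 ± 0.0138, 0.531 ± 0.0118 and 0.391 ± 0.0163 (bootstrap SE over 574 genes). This SE does not measure the spread between wells, so whether the wells differed was not tested. For the signature score the exact permutation p of 0.1 is the smallest the design allows.

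POEA (10 ppb) replicate 1 and, more weakly, Control replicate 1 lay higher in estradiol-responsive genes than the arrays beside them. Array quality or scaling as the whole cause is argued against by genes that the 10 pM arrays of replicate numbers 2 and 3 chose, outside the signature and with the trend in mean level removed, over which the deviations correlated with the 10 pM response at 0.777 ± 0.026 and 0.823 ± 0.025, where 18 reference arrays gave -0.346 to 0.285 (0.436 and 0.232, and at most 0.203, for the 1 nM minus 10 pM profile on which both arrays were singled out). For mixing with 1 nM material the shares were again unequal (differences 0.119 ± 0.0278 and 0.209 ± 0.0319), with the same limit from the common 1 nM response, so mixing stays open. For POEA (10 ppb) replicate 1 an exchange of labels needs a partner without the profile among the estradiol, bisphenol A and 10 ppm glyphosate arrays, but the lowest of those 15 lay 0.22 above the highest reference array. A response to POEA is argued against by the other 5 POEA arrays, whose mean excess was 0.0109. Exposure to about 10 pM estradiol would give a slope near that of the 10 pM arrays on their own response, but it was 0.505 ± 0.0219 for POEA (10 ppb) replicate 1 and 0.395 ± 0.0131 for Control replicate 1 (for the former 0.477 on the response of 10 pM replicates 2 and 3, where 10 pM replicate 1 gave 0.915). The 10 pM replicate 1 array helped choose the genes of these slopes, so its 0.915 can be too high. How much this choice adds was not computed. The SEs in this paragraph are bootstrap SEs over genes and do not measure the spread between arrays. A single wrong label, carry-over of estradiol at a lower dose or mixed-in material may account for the higher levels and stays open. The slopes of the 10 ppm glyphosate arrays, 0.391 to 0.806, enclosed those of both arrays.

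For the counts of calls, splits of the 6 arrays of a comparison into 3 and 3 are only 10, too few for a share under 0.05. The real count and the highest of the other splits were 36 and 0 at 10 pM estradiol, 1158 and 0 at 100 pM, 1104 and 0 at 1 nM, 196 and 1 with bisphenol A, 66 and 0 between the estradiol doses, 4 and 1 between the glyphosate doses, 6 and 0 for bisphenol A against 1 nM estradiol and 289 and 0 for glyphosate against 1 nM estradiol. In the 12 comparisons where limma called 0 clusters (324 to 1398 at an unadjusted p under 0.05) the highest other split gave 2 (1 ppm Roundup against Control), 1 or 0, except 1111 between the Roundup doses. That split joined Roundup (1 ppm G) replicates 1 and 3 with Roundup (1 ppb G) replicate 1, which points to a structure of the arrays apart from dose. On the third principal component, described below, these lay at -9.58, -20.9 and -10.6. Roundup (1 ppm G) replicate 2 lay at 13.7, and Roundup (1 ppb G) replicates 2 and 3 lay at 19.4 and -7.76. Whether this component gave the calls was not tested. Among the splits that part every pair of replicate numbers the highest was 0.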

How the results depend on the processing

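The alternatives without POEA (10 ppb) replicate 1 and Control replicate 1, here the doubted arrays, and the estimated correlation with the block were added after seeing the data. A further quantile normalization and the trend and robust options of eBayes left all 20 counts of calls within 1.5 times. Of 3344 alternatives for 224 called changes of named genes, 2713 kept the call, 631 lost it and 0 turned. Signal near the background limits dim genes. Unless stated, the cause of the changes below was not tested. Comparisons without a second group are against Control.

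With the replicate block the counts were 324, 2470 and 2452 at 10 pM, 100 pM and 1 nM estradiol, 1056 with bisphenol A, 2 at 10 ppm glyphosate, 374 between the estradiol doses, 73 between the glyphosate doses, and 55 for bisphenol A and 1135 for 10 ppm glyphosate against 1 nM estradiol. With only the 6 arrays, which leaves 4 degrees of freedom, they were 0 at 10 pM (unadjusted count 1383 in the fit of all arrays), 401, 440, 15 with bisphenol A, 4 between the estradiol doses, 1 between the glyphosate doses, and 2 and 55 against 1 nM estradiol. All clusters of the table gave 20 at 10 pM estradiol, and bright clusters gave 8 between the glyphosate doses.

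Array weights stopped before convergence, with a weight of 41.9 for Bisphenol A replicate 1. They gave 2128 at 100 pM and 1916 at 1 nM estradiol, 4127 with bisphenol A, 1 at 10 ppm glyphosate, 24 at 1 ppb Roundup, 221 between the estradiol, 80 between the glyphosate and 5 between the Roundup doses, 48 for Roundup against glyphosate at 1 ppb, and 4071 for bisphenol A and 910 for glyphosate against 1 nM estradiol. Without the doubted arrays the counts were 56 at 10 pM estradiol, 3 at 10 ppm glyphosate, 13 between the glyphosate doses and 10 for bisphenol A against 1 nM estradiol. With the block as well they were 437, 2187 and 2281 at 10 pM, 100 pM and 1 nM estradiol, 1054 with bisphenol A, 49 at 10 ppm glyphosate, 404 between the estradiol and 128 between the glyphosate doses, and 68 for bisphenol A and 1101 for glyphosate against 1 nM estradiol.

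Without 1 array, fewer arrays being the cause in part, counts ran from 0 to 37 at 10 pM, 582 to 1168 at 100 pM and 544 to 1125 at 1 nM estradiol, 62 to 237 with bisphenol A, 0 to 1 at 1 ppb glyphosate, 10 ppm glyphosate and 1 ppb Roundup, 14 to 71 between the estradiol, 0 to 5 between the glyphosate and 0 to 2 between the Roundup doses, and 2 to 3 for bisphenol A and 93 to 322 for glyphosate against 1 nM estradiol. All of these fits were made without the block, so the missing array also left the replicate numbers unbalanced between the groups.

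The number of gene lists called was 2 with an estimated correlation at each estradiol dose and with bisphenol A, 1 at 10 ppm glyphosate and 0 in the other 7 herbicide comparisons, where camera's preset had called 1 to 6. An estimated correlation with the block gave 4 at 10 pM, 5 at 100 pM and 5 at 1 nM estradiol, 5 with bisphenol A (adjusted p = 0.000621 for DNA replication, 0.0201 for mitosis and 0.0379 for lysosome genes), 2 at 1 ppb and 2 at 10 ppm glyphosate and 0 in the other 6 herbicide comparisons. Fry called 2 at 10 pM and 5 at 1 nM estradiol, 1 at 10 ppm glyphosate and 0 in the 7 at lower herbicide doses. The block gave 4 at 1 ppb and 3 at 1 ppm Roundup. Bright clusters gave 1 at 100 ppb glyphosate, 0 at 10 ppb POEA, 1 at 1 ppb Roundup and 3 at 100 ppb Roundup. Without the doubted arrays there were 1 and 0 at 1 and 100 ppb glyphosate, 2 and 1 at 10 and 100 ppb POEA, and 1 and 0 at 1 and 100 ppb Roundup. With the block as well there were 2 and 1 for glyphosate, 2 and 2 for POEA, and 1 and 0 at 100 ppb and 1 ppm Roundup. Without the doubted arrays 7 lists turned direction, with adjusted p at 1 ppb glyphosate of 0.871 for estrogen-induced genes, 0.00293 for DNA replication and 0.158 for mitosis, for DNA replication of 0.594, 0.769 and 0.00741 at 1 ppb, 100 ppb and 1 ppm Roundup, and for estrogen-induced genes of 0.928 at 1 ppm Roundup. That fit left Control with replicate numbers 2 and 3 only, so differences between the numbers enter it. With the block as well, 227 of the 252 list results kept their status, 9 gained a call and 16 lost one. No list called in either fit turned there.

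Under each alternative setting the signature genes were chosen anew, and the scores were then compared by group means without block or weights. A changed difference can therefore come from the changed genes. The signature difference of bisphenol A was 0.847 with the block, 1.33 with all clusters, 0.781 with weights, 1.286 without the doubted arrays and 0.876 from the estrogen-induced and estrogen-repressed lists. That of 100 pM estradiol was 1.352, 2.257, 1.264, 2.064 and 1.226 in the same order, 1.647 with only the 6 arrays, 1.472 without the doubted arrays with the block, and 1.644 from the 100 clusters of smallest p. Without the doubted arrays that of 10 ppm glyphosate was 0.526 and that of 10 ppb POEA 0.041, or 0.043 with the block. With the 65 genes kept, that of 10 ppm glyphosate was 0.366 with all arrays and 0.423 without Control replicate 1. With the same 65 genes and without 1 array, that of 10 ppb POEA ran from -0.007 to 0.314.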

Other observations

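The comparisons between replicate numbers, the gene lists tested in them and the tests on the third component were chosen after the data were seen.

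Replicate numbers, compared over 13 arrays each with the group in the model, differed in many transcripts. Against replicate 1, arrays of replicate 2 were higher in CYP1A1, a detoxifying oxidase gene, by 1.36 ± 0.07 (2.57-fold, adjusted p = 3.06e-14, in 13 of 13 groups), and in its relative CYP1B1 (1.95-fold). Of the aryl hydrocarbon receptor targets 5 of 6 rose (adjusted p = 1.97e-06 with an estimated correlation). Of the NRF2 oxidative stress response 16 of 19 rose (adjusted p = 2.49e-07 with an estimated correlation), including the cystine transporter gene SLC7A11 (1.68-fold), AKR1C1 (1.55-fold), the ferritin gene FTL (1.51-fold) and NQO1 (1.33-fold). Of the p53 targets 10 of 20 rose (adjusted p = 0.000813 with an estimated correlation), with GDF15, a stress-induced cytokine gene, at 2.19-fold. In all, 1554 clusters were higher and 1482 lower.

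Arrays of replicate 3 were lower than those of replicate 1 in TXNIP, a glucose-responsive gene, by -1.11 (2.16-fold, adjusted p = 3.63e-16, higher in 0 of 13 groups), and in cell cycle genes, with 33 of 34 mitosis genes and 34 of 39 DNA replication genes lower (adjusted p = 0.0119 and adjusted p = 0.00145 with an estimated correlation). Of the immediate early genes 11 of 12 rose (adjusted p = 0.00763 with an estimated correlation). Against replicate 2, all 20 cholesterol synthesis genes and 7 of 10 fatty acid synthesis genes were lower in replicate 3 (adjusted p = 7.89e-05 and adjusted p = 0.0119 with an estimated correlation). The labels give no date or batch for these numbers, and every treatment group holds 1 array of each.

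The third principal component, with 11.1% of the variance, followed no treatment group, with 19.1% of its own variance between groups and 32.3% between replicate numbers. It set ITGB6, TGFB2, FN1 and THBS1 (ranges over the arrays of 9.27-, 8.48-, 5.71- and 3.54-fold) against CEACAM6, CEACAM5, BPIFB1 and MUC1 (9.95-, 8.34-, 5.96- and 3.28-fold). The component correlated with the SD of the array values at 0.715, but a difference in this spread as the cause is argued against, since the component returned with a correlation of 0.9677 after quantile normalization, which makes the spread equal. Cell density was read from 19 YAP/TAZ target genes, whose mean correlated with the component at 0.497 over 39 arrays (permutation p = 0.001, the only relation in its family, Spearman's rho 0.493 with permutation p = 0.001, and 0.478 without the 2 farthest arrays). The arrays were permuted without regard to replicate number, so this p also reflects differences between the numbers. The value of 0.497 lay between the limits set for and against density, so it does not decide. Within replicate numbers 1, 2 and 3 the correlation was -0.469, -0.722 and -0.469, a criterion outside those limits. These values are opposite in sign to what density as read here would give and argue against it. No other biological explanation was tested.

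With POEA (10 ppb) replicate 1 and Control replicate 1 left out and the replicate number as a block, 10 ppm glyphosate against Control gave 49 calls, 22 higher and 27 lower, of which 48 were called in the same direction at 1 nM estradiol with the same arrays left out. That Control array was chosen for its high estradiol score, so leaving it out moves every comparison against Control toward the estradiol direction. Both comparisons also share the remaining Control arrays, and no value for the overlap without an effect was computed. In the other 7 herbicide comparisons, against the same 2 Control arrays, limma called 0 clusters (603 to 1651 at an unadjusted p under 0.05). GREB1 was higher by 1.37 (2.58-fold, adjusted p = 6.53e-08, 6.53e-08 to 1 over its alternatives) and TFF1 by 0.66 (adjusted p = 0.000664, 0.000664 to 1 over its alternatives), and EPAS1 (-0.68), IL1R1 (-0.61) and APOD (-0.60) were lower. Over this comparison's alternatives the count ran from 0 to 49.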
